A study of Mus musculus with 3 samples.

How the data were processed

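Capture-C, a chromosome conformation capture method in which ligation products of chosen promoters are enriched with oligonucleotide baits and sequenced, was applied to 2 libraries of Ter119+ mouse cells and 1 library of E14-TG2a.IV mouse embryonic stem (ES) cells. Per the labels' protocols, the Ter119+ cells were primary erythroid cells sorted from spleens of mice treated with acetylphenylhydrazine, chromatin was fixed with formaldehyde, cut with DpnII and ligated, and the resulting DNA was sheared before library preparation. The labels do not say whether the 2 Ter119 libraries came from separate animals, so the p-values measure the spread between these 2 libraries, which may be technical. Coordinates are those of build mm9, per the submitters' processing notes. The aligner, its version and the filters on reads are not given in the sources used here.

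The authors deposited a list of read pairs per library and 1 list of 460 captured regions with gene labels, each region widened by 500 bp per the name of that list. Each line of a pair list held the outer coordinates of a pair on 1 chromosome and a count of the read pairs seen with those coordinates, and these deposited counts were whole numbers without normalization. No pair of coordinates was listed more than once, and no line joined different chromosomes. Per the file headers, the second Ter119 list carried the marks of a merge and of a second lane, so that library may itself be pooled. The lists held 5957872, 10077684 and 11529458 distinct pairs for Ter119 1, Ter119 2 and ES, from 12302606, 42912669 and 20570761 read pairs, or 2.06, 4.26 and 1.78 read pairs per distinct pair. Of the distinct pairs, 25.4%, 17.3% and 16.4% touched a captured region. Ter119 1 and Ter119 2 shared 1.91% of the pairs of 5 kb or longer in Ter119 1, against 1.46% shared by Ter119 1 and ES, so the 2 Ter119 lists were not copies of each other. Over 2961 windows the counts of the 2 Ter119 libraries differed by more than sampling noise, with a chi-square of 1.11 per window (p = 4.4e-05), against 2.93 and 2.58 between each Ter119 library and ES, and they were kept as 2 samples.

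A contact was a distinct pair with 1 end in a captured region (the viewpoint) and the other end 1 kb or more outside it. The plan fixed before the data were examined counted reads. The main results here count distinct pairs instead, because copies made by PCR are not independent molecules and the lists already gave 1 line per distinct pair. This change was made after the lists were seen and before any model was fitted. The fit on read pairs, the unit as the plan had it, called 0 windows, and that value is given beside the main count. As the count filter was then applied to read pairs, it tested 9452 windows, and a run on the 3167 windows tested with distinct pairs also called 0. Where a pair joined 2 captured regions it counted for both viewpoints, so windows lying over another captured region repeat pairs of that region's own windows. This held for 234 of the 3167 tested windows.

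Pairs that join near-identical copies of a sequence appear as dense clusters with the same distance between their ends. Contacts were left out where a 400 bp bin of that distance held at least 20 pairs, or 200 pairs within 500 kb, and at least 10 times its flanks. This filter was chosen after seeing the data, and its first form, with 20 pairs at every distance, was replaced before any model was fitted because it also took contacts between neighbouring promoters. It removed 100 clusters at 83 viewpoints and 37.5%, 47.7% and 32.5% of contacts, and left 255671, 184316 and 253754 contacts. Rates and shares of viewpoints are of the contacts left, unless stated otherwise. Reads of near-identical copies (Hba-a2_1 and Hba-a2_2, Hbq1a and Hbq1b, Hbb-b1 and Beta-s) cannot be assigned to 1 copy with certainty, so values of these viewpoints are uncertain between the copies.

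Contacts were counted in 5 kb windows between 5 and 500 kb from each captured region. Viewpoints with fewer than 50 contacts in any library were left out (13 of 460), and windows with 20 or more contacts over the 3 libraries were tested, 3167 windows of 402 viewpoints. The test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), with the log of the viewpoint's contacts in that library as the offset and Benjamini-Hochberg adjustment over all windows at 0.05. With 2 libraries against 1 the fit has 1 residual degree of freedom, and the lone ES library is assumed to vary like the Ter119 libraries. The standard error of a log2 change was taken as its size divided by the square root of the F statistic. Rates are contacts per 1000 contacts of the viewpoint. Ter119 rates are means ± SD over 2 libraries and ES rates carry 95% Wilson intervals, which cover counting error only. On simulated data (1 simulation of 3167 windows for Ter119 against ES, with 200 changed windows), 50 of 50 windows raised 4-fold in Ter119, 21 of 50 lowered 4-fold, 11 of 50 raised 2-fold and 2 of 50 lowered 2-fold were called, with 3 false calls among 2967 unchanged windows, and a simulation without changes gave 0 calls. Only the Ter119 counts were changed, so lowered windows held fewer contacts than raised ones. The minimum of 20 contacts was not applied again after the change. The simulation therefore cannot tell whether the test had less power for windows lower in Ter119. The simulation used the spread estimated from the 2 Ter119 libraries and does not test that estimate.

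Promoter pairs were contacts of either of 2 viewpoints within the captured region of the other, widened by 1 kb, up to 2 Mb away. A contact seen from both viewpoints counted once. The total, used for the offset and the rates, was the contacts of both viewpoints together, and the test was otherwise the same. Replicate agreement was the Pearson and Spearman correlation over windows of log2 contacts per 100000 plus 1, per viewpoint. A set of 5 gene lists were fixed before the data were examined (erythroid genes, pluripotency genes, developmental regulators, other blood lineages and ubiquitous genes), and lists with at least 3 captured genes were tested by permuting membership over genes (100000 resamples, two-sided) on the mean number of windows higher in Ter119 minus those higher in ES. Contact distance and globin shares were given as values, since 2 libraries against 1 cannot give a permutation p below 0.333. The alpha globin region was to be the Nprl3 gene; with no mm9 annotation used here, the interval between the captured regions of Mpg and Nprl3 stands in for it. The beta globin region was the 30 kb beyond the captured region of Hbb-y.

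Named viewpoints followed a rule fixed before the data were examined. It takes every captured globin gene, Nprl3 and Slc25a37 (Sox2, Pou5f1, Nanog and Klf4 have no label among the captured regions), the 10 viewpoints with most windows higher in Ter119, the 10 with most windows higher in ES, and up to 4 members of each gene list with the smallest adjusted p, each with its window of smallest adjusted p. Results of some captured genes that the rule takes, and with them that of the ubiquitous list, are not reported here. Alternatives were other window sizes, spans, scalings, count filters, thinning to equal totals and DESeq2 1.42.0. Added after seeing the data were the ratios of named windows without either Ter119 library, the counts of read pairs (with their own filter and on the windows tested with distinct pairs), the forms of the copy filter, offsets from contacts within 1000 kb or within 500 kb with a distance correction, and runs without the 11 viewpoints of the globin loci. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.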

Results

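The series set the promoter contacts of erythroid cells against those of ES cells, with 460 captured regions, mostly promoters, read at once. There were 2 libraries of Ter119+ cells, which are late erythroid cells, and 1 library of E14-TG2a.IV cells, a mouse ES line. After filtering, 255671 contacts remained in Ter119 1, 184316 in Ter119 2 and 253754 in ES. The ES group had no replicate, so every spread given below comes from the Ter119 libraries. All positions are in mm9.

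The contact landscapes of the captured promoters differed between the cell types, and the globin loci held the viewpoints with most windows higher in Ter119. With edgeR's quasi-likelihood test on distinct pairs, 183 of 3167 windows were higher in Ter119 and 102 were higher in ES. They belonged to 113 and 65 viewpoints, with 26 viewpoints in both sets. Some captured regions overlap, so some changes are counted at more than 1 viewpoint. Ppp1r15a#1 and Ppp1r15a#2, for example, both start at 52780095 on chromosome 7. Windows higher in Ter119 lay at a median of 22.5 kb from the captured region and windows higher in ES at 27.5 kb. Of the 3167 tested windows, 2629 lay within 50 kb, as did 158 of those higher in Ter119 and 74 of those higher in ES. The medians thus reflect largely where windows held enough contacts to be tested. The 11 viewpoints of the globin loci, Nprl3 and Gm5736 included, gave 41 of the windows higher in Ter119 and 14 of those higher in ES. Without windows over other captured regions, 22 and 10 of the globin windows were called. The number of calls rests on the counted unit and on the test. Counting read pairs, as the plan had it, edgeR called 0 of 9452 windows, with 638 at an unadjusted p under 0.05. On the same 3167 windows, read pairs also gave 0 calls, with 391 at that level, while 752 passed it on distinct pairs. DESeq2 on distinct pairs called 17 windows, all higher in Ter119 and all among the 285, and its own filter on mean counts left 343 of the 3167 windows with an adjusted p. After thinning to equal totals edgeR called 0 windows, with 302 at an unadjusted p under 0.05. The offset also set the split, since scaling to contacts within 500 kb gave 377 windows higher in Ter119 and 54 higher in ES and moved the median log2 change of the tested windows from 0.04 to 0.38. The split was 64.2% higher in Ter119 with the viewpoint total and 87.5% with that offset. It also moved with the count filter, to 50.6% with a minimum of 5 contacts, 79.4% with 50 and 61.7% with no filter. With 10 kb windows the majority turned, at 158 higher in Ter119 and 240 higher in ES.

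At the alpha globin locus, which encodes the alpha chains of haemoglobin, the alpha promoters made more contacts with the region towards and within Nprl3, a neighbouring gene whose introns hold the erythroid enhancers of the locus, in Ter119 than in ES. The Hba-a2_1 viewpoint (chromosome 11, 32181948 to 32185207) had its smallest adjusted p 10 to 15 kb below the captured region (32166948 to 32171947), in the window over the captured region of Nprl3. Single windows are given below, unless stated otherwise, for the smallest adjusted p in the direction named, which need not be the largest change. The rate there was 78.4 ± 10.96 contacts per 1000 (SD, n = 2) in Ter119 and 24.3 in ES (95% Wilson interval 17.8 to 33.1), a log2 change of 1.71 (SE 0.17, adjusted p = 8.33e-13), and the window of Hba-a2_1 at 32146948 to 32151947 changed more, by 2.75 on the log2 scale (SE 0.35, adjusted p = 4.93e-12). The ratio of pooled rates in that window was 6.99, or 4.45 without Ter119 1 and 8.33 without Ter119 2. For Hba-a2_2 (32194917 to 32198024) it was the window at 32149917 to 32154916, with 43.4 ± 14.3 per 1000 in Ter119 and 8.83 in ES (5.36 to 14.5), a log2 change of 2.36 (SE 0.31, adjusted p = 1.35e-11). Seen from Nprl3 (32166769 to 32169183), the window at 32179183 to 32184182, which overlaps Hba-a2_1 and holds many of the same pairs, had 137 ± 31.0 per 1000 in Ter119 and 39.8 in ES (29.7 to 53.2), with a log2 change of 1.81 (SE 0.17, adjusted p = 1.11e-15). Hba-x, the embryonic alpha-like gene, had 1 window higher in Ter119, with 24, 5 and 3 pairs in Ter119 1, Ter119 2 and ES. The ratio of its pooled Ter119 rate to the ES rate was 5.24, with an exact counting interval of 1.62 to 26.9 (adjusted p = 0.0333), but it was 2.41 without Ter119 1 and 6.93 without Ter119 2. The call was lost with a minimum of 5 contacts (adjusted p = 0.0861), no count filter (0.213) and a test for a change above 1.5 times (0.0863). For the theta-like genes Hbq1a and Hbq1b, the windows of smallest adjusted p lay over near-identical copies. Their changes were smaller, with log2 changes of 0.63 (SE 0.10, adjusted p = 0.000187) and 0.72 (SE 0.11, adjusted p = 7.15e-05). Both calls rest on the copy filter, which was chosen after seeing the data: without it the log2 changes were 0.03 (adjusted p = 0.868) and 0.33 (adjusted p = 0.623). DESeq2 called neither (adjusted p = 0.322 and 0.197), nor did the fit with no count filter (0.891 and 0.627) or the test for a change above 1.5 times (0.465 and 0.329), and Hbq1a was also lost with the offset within 500 kb plus a distance correction (0.0855). Hbq1b had 4 windows higher in Ter119 and 2 higher in ES. Its window at 32145406 to 32150405 changed more, with a log2 change of 2.01 (SE 0.48, edgeR adjusted p = 0.00134). The ratio of pooled rates there was 4.11, or 2.56 without Ter119 1 and 4.96 without Ter119 2. Other windows of the alpha viewpoints were higher in ES, 5 of Hba-a2_1 and 6 of Hba-a2_2, and they lay on both sides of the genes, among them 32205207 to 32210206 for Hba-a2_1 with 28, 12 and 54 pairs, a log2 change of -1.53 (SE 0.33, adjusted p = 0.000238, and 0.159 with DESeq2).

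**Figure D1:**
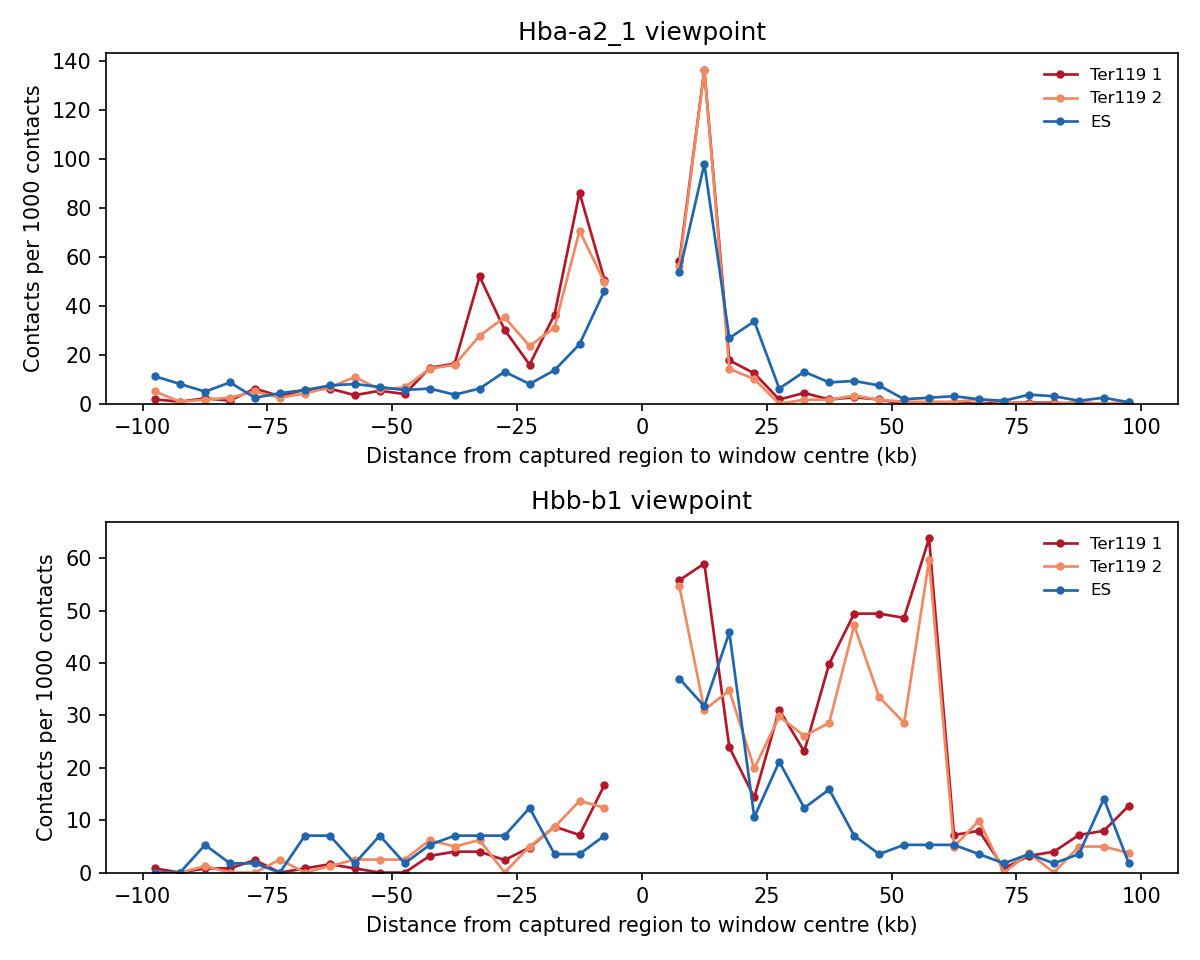
Contacts per 1000 contacts of the viewpoint (vertical axis) in 5 kb windows by distance of the window centre from the captured region in kb (horizontal axis), for Hba-a2_1 and Hbb-b1, with a line per library. For Hba-a2_1 both Ter119 lines lie above ES 12.5 kb below the region, and for Hbb-b1 they lie above ES 57.5 kb above it.

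As a share of their contacts left by the copy filter, the Hba-a2_1 and Hba-a2_2 viewpoints together placed 15.9% ± 1.09 (SD, n = 2) in the interval between Mpg and Nprl3 (32128922 to 32166768) in Ter119. In ES the share was 5.63% (186 of 3302 contacts, 95% Wilson interval 4.897 to 6.47). The 2 Ter119 libraries gave 16.7% (743 of 4457) and 15.1% (357 of 2360), and the ratio of the Ter119 mean to ES was 2.82. The region from 100 kb below to 20 kb above the alpha genes held 68.9% ± 2.78 of the contacts in Ter119 and 57.1% in ES (55.4 to 58.8), a ratio of 1.21. No test was made between the groups for these shares. Their total was small beside the pairs that the copy filter removed. For Hba-a2_1 the filter removed 22179, 23423 and 18582 pairs in Ter119 1, Ter119 2 and ES and kept 2252, 1189 and 1604.

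At the beta globin locus, the adult beta promoters contacted the locus control region, an enhancer cluster beyond Hbb-y, more in Ter119 than in ES. Of their contacts left by the copy filter, the Hbb-b1 and Beta-s viewpoints placed 21.1% ± 2.78 (SD, n = 2) in the 30 kb beyond Hbb-y in Ter119 (chromosome 7, 111003652 to 111033651). In ES the share was 3.00% (35 of 1167 contacts, 95% Wilson interval 2.16 to 4.14), and the ratio was 7.03. The Ter119 libraries gave 23.0% and 19.1%. For Hbb-b1 the filter removed 27121, 29089 and 13532 pairs in Ter119 1, Ter119 2 and ES and kept 1254, 805 and 567. Counting contacts within 500 kb as the total lowered the ratio to 5.41, and a 20 kb region raised it to 9.58. Beta-s (110975098 to 110977640) had 7 windows higher in Ter119 and 0 higher in ES. Its window at 111017640 to 111022639 had 64.5 ± 2.198 contacts per 1000 in Ter119 and 6.67 in ES (2.60 to 17.0), with a log2 change of 3.26 (SE 0.44, adjusted p = 7.73e-09), and 3 of its other windows had larger log2 changes. Hbb-b1 (110961089 to 110963317) had 4 windows higher in Ter119, among them 111018317 to 111023316 with 80, 48 and 3 pairs. The ratio of pooled rates there was 11.7, with an exact counting interval of 3.93 to 57.7 (adjusted p = 2.71e-08). The embryonic genes Hbb-y and Hbb-bh1 had 5 and 2 windows higher in Ter119, all on the side of the adult genes. For Hbb-y, the window at 110975781 to 110980780, over Beta-s, had 62.5 ± 10.1 per 1000 in Ter119 and 9.05 in ES (4.15 to 19.6), a log2 change of 2.80 (SE 0.44, adjusted p = 5.78e-08). For Hbb-bh1, the window at 110980724 to 110985723 had 73.1 ± 3.94 and 19.4 (11.4 to 33.0), a log2 change of 1.91 (SE 0.34, adjusted p = 4.35e-06).

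**Figure D2:**
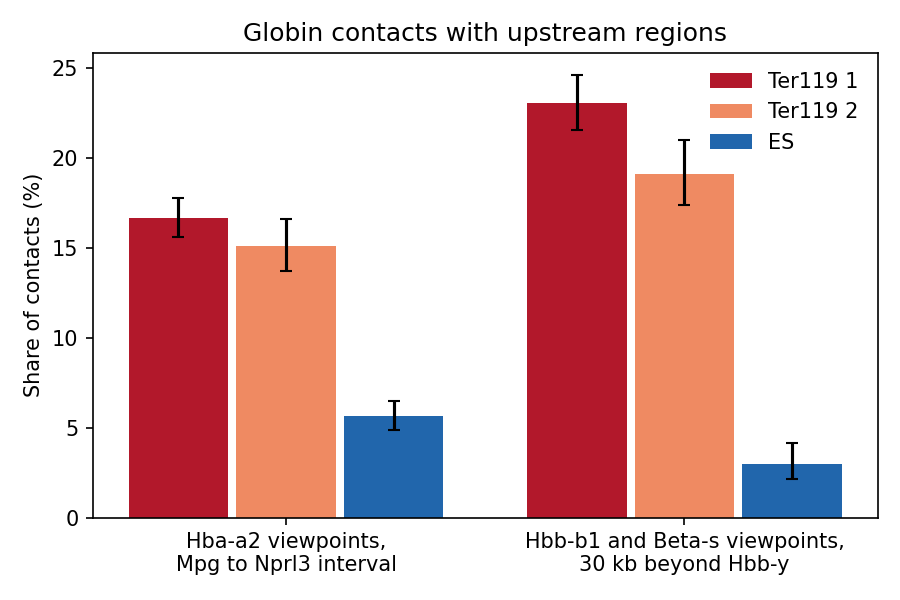
Share, in percent, of the contacts left by the copy filter (vertical axis), with a bar per library and 95% Wilson intervals. It is given for the Hba-a2 viewpoints in the Mpg to Nprl3 interval and for the Hbb-b1 and Beta-s viewpoints in the 30 kb beyond Hbb-y. Both Ter119 libraries lie above ES in both regions, at 16.7% and 15.1% against 5.63% and at 23.0% and 19.1% against 3.00%.

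Of the erythroid list, 65 genes were captured. Windows rose in Ter119 alone at 21 of them, were higher in ES alone at 3, went both ways at 5, and none passed the test at 36, of which 6 had no window deep enough to test. The list had 57 windows higher in Ter119 and 20 higher in ES among 531 tested, or 65 and 24 when adjusted over the list alone. Slc4a1, the anion exchanger of the red cell membrane, had 3 windows higher in Ter119 and 1 higher in ES. Its window at chromosome 11, 102233282 to 102238281, had 98.7 ± 9.07 contacts per 1000 in Ter119 and 19.1 in ES (10.7 to 33.9), a log2 change of 2.37 (SE 0.39, adjusted p = 4.62e-07). Slc25a37, the mitochondrial iron importer mitoferrin, had 1 window higher in Ter119 (chromosome 14, 69919243 to 69924242), with 27, 8 and 2 pairs. The ratio of pooled rates was 6.67, with an exact counting interval of 1.71 to 57.3 (adjusted p = 0.026), and the call was lost with the offset within 500 kb plus a distance correction (adjusted p = 0.11), a minimum of 5 contacts (0.0618), no count filter (0.151) and a test for a change above 1.5 times (0.071). The ratio was 4.15 without Ter119 1 and 8.14 without Ter119 2. Per gene, the list averaged 0.55 more windows higher in Ter119 than in ES, against 0.12 for the 363 other genes (permutation test, adjusted p = 0.004). That difference no longer passed with 10 kb windows (adjusted p = 0.39), with 1 viewpoint per 500 kb (adjusted p = 0.38), without the globin loci (adjusted p = 0.14), with the offset from contacts within 500 kb (adjusted p = 0.15), or for the share of genes with any changed window (adjusted p = 0.2).

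Few genes of the other lists were captured. For the other blood lineages, 6 were captured, with 1 window higher in Ter119 and 2 higher in ES, or 2 and 3 when adjusted over the list alone. Meis1, a homeobox gene of blood progenitors, had both windows higher in ES. The window 140 to 145 kb below the captured region (chromosome 11, 18773003 to 18778002) had 5.48 ± 2.75 contacts per 1000 in Ter119 and 62.7 in ES (49.4 to 79.3), a log2 change of -3.56 (SE 0.52, adjusted p = 6.53e-09). The change was smaller with distance correction, at -2.73, and with the offset within 500 kb plus distance correction, at -2.29, and passed in both (adjusted p = 4.06e-05 and 0.00295). Runx1_2, a viewpoint of the blood transcription factor Runx1, had the window higher in Ter119, with 13, 12 and 1 pairs and a ratio of 10.7 (exact counting interval 1.76 to 441, adjusted p = 0.0195). That call was lost with a minimum of 5 contacts (adjusted p = 0.0777), no count filter (0.19) and a test for a change above 1.5 times (0.0537). Gata2 and Sfpi1 did not pass, with log2 changes of -1.58 (SE 0.62, adjusted p = 0.0902) and -0.08 (SE 0.65, adjusted p = 0.956). Of the 3 captured developmental regulators, Eomes, a T-box factor of early development, had 1 window higher in ES (chromosome 9, 118300638 to 118305637), with 1, 0 and 26 pairs. The ES rate over the pooled Ter119 rate was 22.0, with an exact counting interval of 3.62 to 903 (adjusted p = 0.000208), and the fitted log2 change moved from -4.24 to -3.00 with the offset within 500 kb plus distance correction (adjusted p = 0.0421). Without Ter119 2 the ratio was 12.9, and without Ter119 1 no Ter119 pair was left. Hoxa7 and Hoxa9 had log2 changes of -1.81 (SE 0.65, adjusted p = 0.0547) and -1.46 (SE 0.58, adjusted p = 0.0902), and adjusted over the list alone 3 windows were higher in ES. With the offset within 500 kb their log2 changes were -0.80 (adjusted p = 0.468) and -0.34 (adjusted p = 0.752), and that of Gata2 was -0.90 (adjusted p = 0.373). The ratio of rates of Hoxa9, ES over Ter119, was 2.79, or 4.27 without Ter119 1 and 2.23 without Ter119 2. Klf2 was the only captured pluripotency gene, with a log2 change of -0.38 (SE 0.63, adjusted p = 0.76), and the ratio of its ES to its Ter119 rate was 0.944 without Ter119 1 and 1.82 without Ter119 2. The mean number of windows did not differ from that of other genes for the developmental regulators or the other blood lineages (permutation test, adjusted p = 0.4 for each). The permutation held 3 and 5 genes of these lists, which gives it little power. Of the other blood lineages only 4 genes had a tested window.

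Outside the lists, the viewpoints with most windows higher in Ter119 included Hipk2, a nuclear kinase gene, and Tnfrsf14, a receptor gene of the TNF family. Hipk2 had 4 such windows, all on the same side of the captured region, and 1 lay at chromosome 6, 38867388 to 38872387, with 16, 8 and 1 pairs and a ratio of 17.3 (exact counting interval 2.82 to 711, adjusted p = 0.00144). Tnfrsf14 had 3 adjoining windows, among them chromosome 4, 154286461 to 154291460, with 52.3 ± 12.3 contacts per 1000 in Ter119 and 16.6 in ES (10.1 to 27.3), a log2 change of 1.66 (SE 0.39, adjusted p = 0.000891). Besides the alpha globin genes and Meis1, the viewpoints with most windows higher in ES included Mxd3, Mpp2, Neat1, Tinagl1, B230312A22Rik and Spata13. Mxd3, a gene of the MYC, MAX and MAD network, had a log2 change of -3.27 (SE 0.52, adjusted p = 1.25e-07) at chromosome 13, 55493208 to 55498207. Neat1, a long noncoding RNA gene, had a log2 change of -1.51 (SE 0.32, adjusted p = 0.000231) at chromosome 19, 5818461 to 5823460, and 1 other window higher in Ter119. Mpp2, Tinagl1 and B230312A22Rik had 3 windows higher in ES each, with log2 changes of -1.89, -1.97 and -2.79 in those of smallest adjusted p (SE 0.38, 0.43 and 0.75). The B230312A22Rik window, 372.5 kb away, was no longer called with distance correction (-1.96, adjusted p = 0.104), with the offset within 500 kb (-2.01, adjusted p = 0.0636) with both (-1.53, adjusted p = 0.235) or with no count filter (adjusted p = 0.0753), and the Mpp2 change moved to -1.16 with the offset within 500 kb (adjusted p = 0.0203). Their ES rates were 7.28 and 3.74 times the pooled Ter119 rates, or 4.84 and 2.57 times without Ter119 1 and 12.2 and 5.95 times without Ter119 2. Spata13 had 2 windows higher in ES, but its window of smallest adjusted p was higher in Ter119, with a log2 change of 1.61 (SE 0.30, adjusted p = 8.08e-06). With DESeq2 the windows given for Hbb-bh1, Neat1, Spata13 and Tnfrsf14 did not pass (adjusted p = 0.0537, 0.17, 0.107 and 0.159), with log2 changes of 1.91, -1.52, 1.59 and 1.66. On read pairs none of the 25 windows of the naming rule that passed on distinct pairs passed the threshold, and all 25 kept their direction. Read pairs recount the same molecules, so the kept direction is not separate evidence.

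Counted as pairs of captured promoters with a 1 kb margin, contacts did not pass the test for any pair, although contacts between some of these promoters passed as 5 kb windows above (Hba-a2_1 with Nprl3, Hbb-y with Beta-s). Of 102 pairs tested within 2 Mb, edgeR called 0, with 31 at an unadjusted p under 0.05, 29 of them higher in Ter119, and DESeq2 called 2, both higher in Ter119. The smallest adjusted p was 0.0677. It was shared by 8 pairs, among them Nprl3 with Hba-a2_1 and Rnf123 with Apeh, chosen after their values were seen. Per 1000 contacts of both viewpoints together, Nprl3 with Hba-a2_1 had 72.2 ± 12.4 in Ter119 and 23.1 in ES (18.1 to 29.5). Rnf123 with Apeh had 77.7 ± 5.89 and 20.8 (13.3 to 32.2). These rates cannot be set beside those of windows, whose total is that of 1 viewpoint. In 73 of the 102 pairs both Ter119 libraries lay above ES and in 13 both lay below, where chance places 33.3% on each side. The pairs are not independent, so these counts carry no test. Many share a captured region, and all share the 1 ES library. Some hold the same molecules, such as Nup62 with Tbc1d17 and Atf5 with Tbc1d17, each at 33, 34 and 34 pairs in Ter119 1, Ter119 2 and ES. With a distance correction the median log2 change of the pairs fell from 0.74 to 0.15. The number at an unadjusted edgeR p under 0.05 fell from 31 to 21. That correction was learned from these same pairs, so it takes out a rise they share, whatever its cause. The fall therefore does not show that distance accounts for the tilt towards Ter119. The call was not stable, since 1 pair was higher in Ter119 with the distance-corrected offset, 16 without the 1 kb margin, 34 with a 5 kb margin (and 6 higher in ES), and 18 with 5 or more contacts per pair. The edgeR prior degrees of freedom were 2.097 for the 102 pairs and infinite for the windows and for both other margins, and the reason for the difference in calls was not tested.

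The distance over which promoters made their contacts differed between the cell types across most viewpoints. Pooled over viewpoints, contacts 100 to 500 kb away made up 11.7% ± 0.232 (SD, n = 2) of all contacts in Ter119 and 21.4% in ES (95% Wilson interval 21.2 to 21.5). This share was lower in both Ter119 libraries than in ES at 418 of 447 viewpoints and higher in both at 13. Contacts more than 10 Mb away made up 26.7% ± 1.71 in Ter119 and 16.0% in ES (15.8 to 16.1), with 421 viewpoints higher in both Ter119 libraries and 3 lower. Between 5 and 20 kb the shares were 14.5% ± 0.436 and 14.3% (14.2 to 14.4), a difference within the spread of the Ter119 libraries. The median share per viewpoint within 500 kb was 53.6% ± 1.07 in Ter119 and 66.8% in ES, and within 10 kb it was 18.0% ± 0.277 and 18.6%. Within 100 kb the medians were 41.9% ± 0.760 and 45.1%, and within 1000 kb they were 57.5% ± 2.04 and 72.9%. No test between groups was made for these shares.

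**Figure D3:**
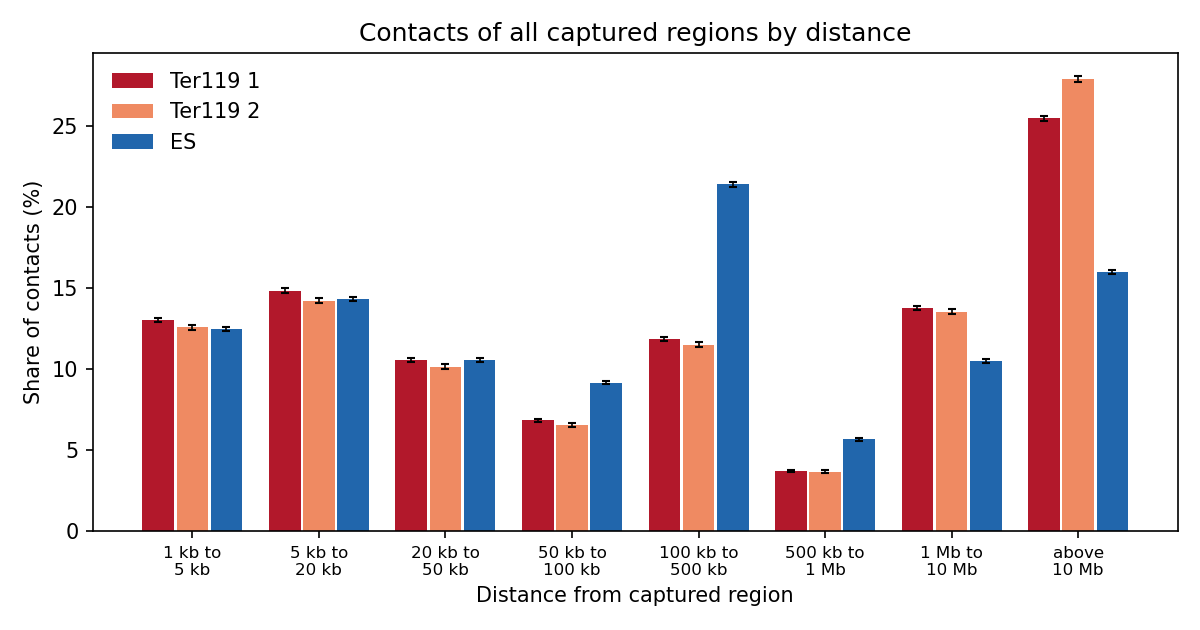
Share of all contacts in percent (vertical axis) by distance from the captured region (horizontal axis), with a bar per library and 95% Wilson intervals. Between 100 and 500 kb the Ter119 libraries reached 11.8% and 11.5% against 21.4% in ES, and above 10 Mb they reached 25.4% and 27.9% against 16.0%.

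The profiles of single viewpoints agreed more between the Ter119 libraries than between cell types. The median Pearson correlation over 5 kb windows was 0.466 between the Ter119 libraries, 0.390 between Ter119 1 and ES and 0.375 between Ter119 2 and ES, over 447 viewpoints, and the median Spearman correlations were 0.490, 0.439 and 0.415. The Ter119 pair had the highest correlation of the 3 at 307 viewpoints. Windows are not independent replicates, so these correlations carry no p-value.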

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

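Some tests were chosen after the result was seen. These were the tests of X copy number, of a genome-wide change, and of a fall at the genes of the erythroid list alone. So was the test of random ligation as the source of the lower 100 to 500 kb share. Set before the result was seen were the comparison of the erythroid list with other genes and the test of random ligation beyond 10 Mb.

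Pairs without a captured end, which enter none of the comparisons of promoters, held more X chromosome pairs in Ter119 than in ES. Relative to the autosomes, the X share was 1.73 times that of ES in Ter119 1 and 1.79 times in Ter119 2, while the ratios of the 19 autosomes ran from 0.957 to 1.06. Y pairs numbered 0 in Ter119 1, 25 in Ter119 2 and 16895 in ES, and a count of 0 allows a share of up to 7.05e-05% of the autosomal pairs. X copy number was named as an explanation after these values were seen. The mean ratio of 1.76 is the value that prompted it and so does not test it, and the explanation stays open. The sex of the animals is not given in the labels used here.

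In the same pairs, those spanning more than 10 Mb over those of 5 to 20 kb were 2.51 times the ES value in Ter119 1 and 2.65 times in Ter119 2. The captured viewpoints showed the same direction, at 1.54 and 1.76 times. Random ligation, which joins ends without regard to distance, predicts contacts that are nearly flat beyond 10 Mb. This was tested at the captured viewpoints. Per Mb of chromosome available, their contacts at 10 to 20 Mb were 2.94 times those at 40 to 60 Mb in Ter119 on average (3.19 and 2.68). In ES they were 1.88 times. These values argue against random ligation as the source of the excess at captured viewpoints. The pairs without a captured end were not tested in this way. A difference in chromosome folding between the cell types, or another difference between the preparations, stays open and was not tested.

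For the lower 100 to 500 kb share in Ter119, dilution by random ligation would leave the ratio of 100 to 500 kb contacts to 5 to 20 kb contacts as in ES, yet that ratio in Ter119 was 0.537 times the ES value on average, which argues against it. A fall at the genes of the erythroid list alone is argued against by the genes outside it, whose mean log2 change was -0.87. Those other genes include Beta-s, Hbq1a and Hbq1b and were not sorted by their activity in erythroid cells. A fall confined to erythroid promoters in a wider sense therefore stays open. The erythroid list differed from the other genes by -0.26 on the log2 scale (permutation p = 0.00073, 95% bootstrap interval -0.42 to -0.10). The permutation treats genes as independent, although neighbouring captured genes share contacts and all genes share the 1 ES library. The share is of all contacts of a viewpoint, so a rise of nearer contacts also lowers it. Without the globin loci, a run added later, the difference was -0.20 (permutation p = 0.0097), so part of the pattern may follow the kind of promoter. Whether the rest is a genome-wide change of folding or of library preparation could not be settled: for pairs without a captured end, the ratio of 100 to 1000 kb pairs to 5 to 20 kb pairs was 0.873 and 1.15 times the ES value with all pairs, and 0.756 and 0.809 times (mean 0.782) without 2 kb cells that held more than 2 pairs, a filter added after the first values were seen. Cell type and preparation cannot be told apart with 1 ES library.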

How the results depend on the processing

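The number of calls depended on the settings more than the direction of the 30 named windows did. These windows were picked by adjusted p in the same libraries, so a kept direction is not separate evidence. Of those that each alternative on the same 5 kb windows held (13 at least 20 kb away, 17 with 50 contacts, 24 after thinning, 25 without captured regions, otherwise 30), Sfpi1 alone changed sign, from a log2 change of -0.08 to 0.53 with the offset from contacts within 500 kb or within 1000 kb and to 0.11 with that within 500 kb plus a distance correction. The main counts were 183 windows higher in Ter119 (113 viewpoints) and 102 higher in ES (65 viewpoints). Read pairs, the unit of the original plan but run here as an added alternative, gave 0 and 0 windows (0 and 0 viewpoints), as did read pairs on the windows tested with distinct pairs (0 and 0, 0 and 0 viewpoints) and thinning to equal totals (0 and 0, 0 and 0 viewpoints). DESeq2 gave 17 and 0 windows (10 and 0 viewpoints), with an adjusted p for 343 of 3167 windows and for 14 of the 30 named ones. The edgeR prior degrees of freedom were infinite in the main fit, 6.54 on read pairs, 4.316 on read pairs on the same windows and 0.85 after thinning, so the main calls treat a spread learned from 1 residual degree of freedom as known; the cause of the lost calls was not tested further. The offset from contacts within 500 kb gave 377 and 54 windows (192 and 33 viewpoints), that within 1000 kb, added after seeing the data, 314 and 58, and no count filter 74 and 46 (49 and 36 viewpoints). A minimum of 50 contacts left 143 and 37 windows (89 and 30 viewpoints), and 5 contacts gave 123 and 120. A change above 1.5 times gave 87 and 42 (56 and 31 viewpoints), adjusted p of 0.01 gave 100 and 48, and windows at least 20 kb away gave 105 and 69. With 2 kb windows 130 and 34 were called (66 and 27 viewpoints), and with 10 kb windows 158 and 240 (105 and 124 viewpoints), which turned the majority. The 2 kb and 10 kb windows also started farther from the captured region than the 5 kb ones, so the distances tested differed too. The share higher in Ter119 was 64.2% in the main fit, 58.6% with TMM, 71.5% with distance correction, 84.4% and 87.5% with the offsets within 1000 and 500 kb. With a minimum of 5 or 50 contacts it was 50.6% and 79.4%, and with no count filter 61.7%. Further alternatives added after seeing the data gave 148 and 92 without the copy filter, 190 and 109 with its first form, 181 and 82 with the offset within 500 kb plus a distance correction, and 142 and 88 without the globin viewpoints. Windows to 1000 kb changed nothing, as no farther window reached 20 contacts.

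The erythroid list difference of 0.438 windows per gene (adjusted p = 0.004) fell below the threshold at 0.219 with 10 kb windows (adjusted p = 0.39), 0.201 with 1 viewpoint per 500 kb (0.38), 0.241 without the globin viewpoints (0.14), 0.279 with the offset within 500 kb (0.15) and 0.118 for the share of genes (0.2); it passed with distance correction (0.017) and DESeq2 (0.015). The cause was not tested. Promoter pairs higher in Ter119 numbered 0 in the main fit, 16 with no margin, 34 with a 5 kb margin (6 higher in ES), 18 with 5 or more contacts, 2 with DESeq2 and 1 with distance correction. The difference of Ter119 minus ES in the median share within 100, 500 and 1000 kb was -4.12, -15.3 and -17.5 points without contacts under 5 kb, against -3.17, -13.2 and -15.4. The beta globin ratio of 7.03 became 5.41 with the total within 500 kb and 9.58 with a 20 kb region.

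Leaving out either Ter119 library gave -0.85 to -0.46 points within 10 kb, -3.70 to -2.63 within 100 kb, -13.9 to -12.4 within 500 kb, -16.8 to -13.9 within 1000 kb, alpha ratios of 2.69 to 2.96 and beta ratios of 6.37 to 7.68. For the windows it leaves no residual degrees of freedom, so no test was run; ratios of rates, added after seeing the data, changed direction for Klf2 and Sfpi1 (neither called), at 0.944 and 0.877 for ES over Ter119 without Ter119 1. No paired analysis was possible because the ES group has 1 library and shares fewer than 2 replicate numbers with Ter119. Not run were counts of restriction fragments, as no map of fragments was used here, and the share of contacts on other chromosomes, as no line joined 2 chromosomes. Depth limits the test, since the median tested window held 33 contacts over 3 libraries.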

Other observations

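Several erythroid list genes outside the naming rule also had changed windows on distinct pairs; they were chosen after their values were seen, and all rest on few pairs. Car2, carbonic anhydrase of the red cell, had 27, 34 and 11 pairs in Ter119 1, Ter119 2 and ES in the window at chromosome 3, 14875057 to 14880056, a log2 change of 2.08 (SE 0.45, edgeR adjusted p = 0.000231, and 0.0954 with DESeq2). Rhag, a Rh-associated membrane protein gene, had a log2 change of 2.14 (SE 0.66, edgeR adjusted p = 0.0204) at chromosome 17, 40959985 to 40964984, with 28, 20 and 4 pairs, and was not called with no count filter (0.118) or a test for a change above 1.5 times (0.0688). Epor, the erythropoietin receptor gene, went both ways, with 15, 18 and 5 pairs at chromosome 9, 21804451 to 21809450 (log2 change 1.93, SE 0.65, edgeR adjusted p = 0.039) and 2, 4 and 20 pairs at 21789451 to 21794450 (log2 change -2.45, SE 0.63, edgeR adjusted p = 0.00335). The first was not called with a minimum of 5 contacts (0.088), no count filter (0.222) or a test for a change above 1.5 times (0.109). For the second, ES over pooled Ter119 was 5.66, or 3.99 without Ter119 1 and 9.01 without Ter119 2. Alas2, the erythroid enzyme of the first step of haem synthesis, was higher in ES, with 14, 4 and 16 pairs at chromosome X, 146988137 to 146993136 (log2 change -1.68, SE 0.57, edgeR adjusted p = 0.0413). ES over pooled Ter119 was 3.21, or 5.90 without Ter119 1 and 2.44 without Ter119 2. The call was lost with the offset within 500 kb (0.14), within 1000 kb (0.127) or within 500 kb plus a distance correction (0.0608), with a minimum of 5 contacts (0.0982), no count filter (0.253) and a test for a change above 1.5 times (0.119). Alas2 lies on the X chromosome, whose share of pairs differed between the cell types. The offset, the total of the same viewpoint, only scales the counts. Whether the X difference bears on this window was not tested. With counts of read pairs, and after thinning to equal totals, edgeR called 0 windows, these included.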
